A study of Mus musculus with 2 samples.

How the data were processed

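The series holds 2 ChIP-seq libraries made with an antibody against EP300 from liver of strain B6NCrl mouse embryos at 14.5 days, with both sexes pooled. Per the labels, the livers were pulverized and pooled from several dissections. The libraries are numbered as biological replicates 1 and 2 in the labels but carry the same biosample label. Nothing in the labels says that they came from separate animals, so their spread may be technical.

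The starting point was the authors' deposited peak lists in narrowPeak format on assembly mm10. Per the file listings deposited with each library, each library's list came from its filtered alignments and 1 control file, a different one for each, and the pooled list came from both libraries and both controls. The optimal and conservative lists were made from these 3 lists and 1 further file. The aligner, the peak caller and the threshold are not given in the sources used here. Peak signal, as deposited by the authors, is the peak caller's value for each peak and is never negative; each list is on its own scale. The score, as deposited by the authors in the IDR lists, is a whole number on a scale that ends at 1000, and 11856 optimal peaks had that value. The peaks of the optimal and conservative lists were all entries of the pooled list. No list gives read totals, so depth is unknown, and the precision given here is that of counts of peaks and genes.

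Peak coordinates were kept as deposited and are printed counted from 1. They were set on the GRCm38 sequence, which is mm10, and the GENCODE vM21 annotation; no peak ran past the end of a chromosome. Gene and motif results used the 17043 optimal peaks on the 19 autosomes and X; the 12 on unplaced contigs were left out. A promoter peak had its summit within 1 kb of any annotated TSS, and the remaining summits were placed, in order, in coding exons, other exons or untranslated regions, introns or intergenic sequence. A gene had a peak when a summit lay within 20 kb of any of its TSSs.

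The design, the gene lists, the motifs and the processing alternatives were fixed before the data were examined. Replicates were compared by the share of top peaks with a top peak of the other library within 100 bp, against 1000 circular shifts of at least 1000 kb. Promoter share and clustering (another summit within 12.5 kb) were compared with 1000 random placements on the same chromosomes outside assembly gaps. Each of 21 gene lists was tested with a two-sided Fisher's exact test against all other protein-coding genes, and 481 of the 482 listed genes were in the annotation. Peak strength near each list with at least 5 members with a peak was tested with 100000 random draws of genes. Each of 24 motifs, written as consensus sequences and searched on both strands within 100 bp of the summit, was tested with an exact McNemar test against 2 flanks at 400 to 500 bp, together as long as the centre. Benjamini-Hochberg adjustment was over lists or motifs, at a threshold of 0.05. Intervals on shares are 95% Wilson intervals, and that on Spearman's rho came from 200 bootstrap samples of peaks. All p-values are over peaks or genes and not over animals, and neighbouring genes can share a peak.

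Genes were named by a rule fixed in advance. From each list past the threshold it took the 4 members with the strongest peak and up to 2, alphabetically, without a peak within 50 kb, and from each other list the member with the strongest peak. It added the genes nearest to the 12 strongest peaks, the genes of the 8 clusters with the most peaks and of the 8 with the highest summed signal, and a fixed set of 16 genes: Ep300, Crebbp, Gata1, Klf1, Tal1, Hbb-bs, Hba-a1, Slc4a1, Alas2, Alb, Afp, Hnf4a, Cebpa, Apoa1, Syn1 and Myh6. Other genes are named to complete a small count or to say where a peak lies, and were chosen after their values were seen. Some genes that the rule took are not reported here.

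The alternatives were the conservative list, optimal peaks above the median signal, as many top peaks of the pooled list, and as many top peaks of each library alone, which leaves out the other. For genes they were windows of 5 kb and 50 kb, each peak given to its nearest gene within 100 kb, distal peaks alone, 1 gene per list in 100 kb, and a logistic regression on gene length and on the number of TSSs nearby. For location they were promoter windows of 500 bp and 2.5 kb, TSSs of protein-coding genes, stitching at 5 kb and 25 kb and placements that keep the distance to the TSS. For motifs they were a centre of 50 bp on either side, a shuffle that keeps dinucleotides and a difference in log odds, to which 0.5 was added per count. Leaving out the 1071 peaks within 500 bp of a stronger one was added after seeing the data, as were draws for peak strength in which each gene was replaced by one with about as many peaks within 20 kb, in bins of 2 per doubling.

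The tests were tried on simulated data. Of 100 planted gene lists over the 21728 genes, 100 were recovered, and of 100 random lists 0 were called. Background peaks were placed at random and list genes were drawn at random. The runs thus hold neither the clustering of the real peaks nor lists of neighbouring genes, and do not test false calls where genes share a peak. For peak strength, 15 of 15 planted lists were recovered and 0 of 15 random lists called. An HNF4A site planted in 19.6% of 5000 sequences came back as an excess of 19.7 points, with 0 of 23 other motifs called. Of 20 random sets of positions, the promoter share was called in 1 and clustering in 0. These sets were placed in the same way as the random placements they were compared with, so they check the computation only. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.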

Results

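EP300 is a histone acetyltransferase and transcriptional coactivator that is recruited to active enhancers and promoters. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in liver of mouse embryos at 14.5 days of development. At this age the liver is the main site of red blood cell formation, so erythroid precursors share the organ with hepatocytes and with endothelial, stromal and other blood cells. The 2 libraries formed 1 group, without a second tissue, age or genotype, and the comparisons therefore ask where in the genome EP300 was found and which genes and sequences lay near it. The authors deposited a list of 300000 peaks for each library, a pooled list of 300000 peaks, and 2 lists of reproducible peaks filtered by the irreproducible discovery rate (IDR), called optimal and conservative. Read totals are not given in the files, so the depth of each library is unknown.

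The optimal list held 17055 peaks with a median width of 340 bp, and 17043 of them lay on the assembled chromosomes of mm10. The signal of a peak is the authors' own value and was used only to describe and rank peaks within a list; it ran from 5.20 to 570.3 in the optimal list, with a median of 38.5. The conservative list held 15728 peaks, of which 13376 were also in the optimal list. Shared peaks had a median signal of 50.5, against 17.7 for the 3679 peaks found only in the optimal list.

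Strong EP300 peaks recurred in both libraries and weak ones often did not. The peak with the highest signal, 13049 bp from the transcription start site (TSS) of Gfi1b, ranked 1 in each library. The 2 strongest peaks at Nprl3, whose introns hold the upstream enhancers of the alpha-globin genes, ranked 2 and 3 in replicate 1 and 6 and 47 in replicate 2. In contrast, the strongest optimal peak near Hnf4a, a transcription factor gene of hepatocytes, ranked 61621 in replicate 1 and 27347 in replicate 2. That near the fetal serum protein gene Afp had no replicate 2 summit within 100 bp. Peaks near other hepatocyte genes did recur. The strongest near Fah ranked 530 in replicate 1 and 252 in replicate 2, and that near Alb 15734 and 15247. Summits from both libraries lay within 100 bp of 14360 optimal peaks (84.3%), of all peaks in the strongest decile (100%) and of 27.2% in the weakest decile.

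Of the 17031 top peaks of replicate 1 on the chromosomes, 11534 (67.7%, 95% Wilson interval 67.0 to 68.4) had a top peak of replicate 2 within 100 bp, when as many top peaks were taken per library as the optimal list holds. Shifting the summits of replicate 2 along the chromosomes gave 0.137% ± 0.0288 (mean and SD of 1000 shifts; one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The share was 42.9% with summits within 25 bp and 42.0% with 2 times as many top peaks. Across the 14360 peaks found in both libraries, the signals correlated with a Spearman's rho of 0.853 (95% bootstrap interval 0.848 to 0.859) and, on the log2 scale, a Pearson's r of 0.869. These peaks were chosen for a summit in both libraries, from a list filtered by IDR. The coefficients therefore describe the chosen peaks and do not test the agreement. They are also across peaks, which are not independent replicates, and intervals on counts of peaks cover counting error only.

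**Figure D1:**
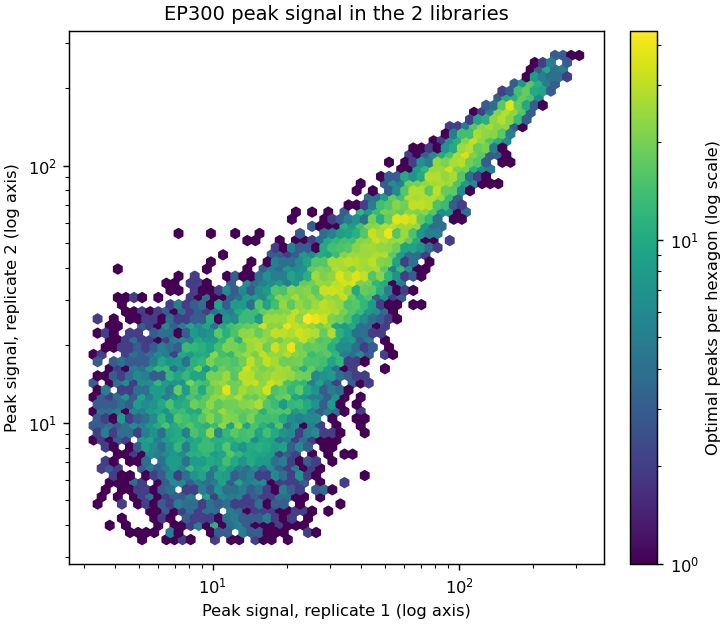
Peak signal in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), in the peak caller's signal units, for the 14360 optimal peaks with a summit of both libraries within 100 bp; colour gives the number of peaks per hexagon. The cloud is narrow at high signal and wide at low signal, and Spearman's rho is 0.853.

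The strongest EP300 peaks lay at regulators and products of the red blood cell. The first was 13049 bp from the TSS of Gfi1b, a zinc finger repressor of erythroid and megakaryocytic development, on chromosome 2 from 28602154 to 28602534 in an intergenic region (signal 570.3). The second, with a signal of 544.1, lay in an intron of Nprl3 on chromosome 11 from 32245578 to 32246036. A peak on chromosome 7 from 103877126 to 103877488, between the beta-globin genes and the olfactory receptor gene Olfr66, had a signal of 525.5. Gypc, which encodes a glycophorin of the red cell membrane, had an intronic peak of 509.5 on chromosome 18 from 32542334 to 32542784. Zfpm1, the gene of the GATA1 cofactor FOG1, had an intronic peak of 505.5 on chromosome 8 from 122309295 to 122309688.

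Other peaks among the first 12 lay in introns of Sugct (signal 523.5) and of Smtnl1 near Ube2l6 (512.3), and in intergenic regions whose nearest genes were Picalm (518.8) and Lao1 (533.1 and 515.6). Their summits were 67177 bp from Picalm and 63215 and 71415 bp from Lao1. The last of the 12, with a signal of 503.0, lay within 1 kb of an Nprl3 TSS. A GATA motif (WGATAR) was present within 100 bp of the summit in all 12, and a composite of an E-box and a GATA site in 4 of them, at Nprl3, Olfr66, Ube2l6 and Gypc.

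Several loci carried long runs of peaks. Stitching neighbouring summits gave 9757 clusters, of which 6163 were single peaks, 460 held at least 5 peaks and 37 held at least 10. By summed signal, the first 3 were at Tbxas1 (20 peaks, 2366.5), at Nprl3 and the alpha-globin genes (20 peaks, 2327.6) and at Zfpm1 (20 peaks, 2264.6). Clusters with nearest genes Olfr66 (8 peaks), Picalm (20), Lao1 (8) and Hist1h4f (31) were also among the first 8. By number of peaks, the longest were at the histone gene Hist1h4f and at Slc4a1, which encodes the anion exchanger band 3 of the red cell membrane (23 peaks). The clusters at Hist1h4b (20 peaks) and Aqp1 (18), a water channel gene of red cells and several epithelia, were also among the 8 with the most peaks. Of these 8, the 2 histone clusters had the most promoter peaks and the fewest peaks with a GATA motif: at Hist1h4f 21 of the 31 peaks were at promoters and 6 had the motif, and at Hist1h4b 17 and 5 of 20. The other 6 ran from Slc4a1, with the motif in 10 of its 23 peaks and 5 at promoters, and Nprl3, with 12 and 7 of 20, to Zfpm1, with 18 and 3 of 20.

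At the alpha-globin locus, 8 of the 20 peaks lay in the body of Nprl3, 5 of them with a GATA motif. Their signals reached 544.1, whereas the strongest peak downstream of Hba-x had a signal of 101.2, on chromosome 11 from 32293519 to 32293858. At the beta-globin locus, 8 peaks with signals from 13.2 to 525.5 lay between Hbb-y and Olfr66, the interval that holds the locus control region, and 7 of them had a GATA motif. The adult gene Hbb-bs had a peak of 221.4 on chromosome 7 from 103827870 to 103828194, over its promoter.

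**Figure D2:**
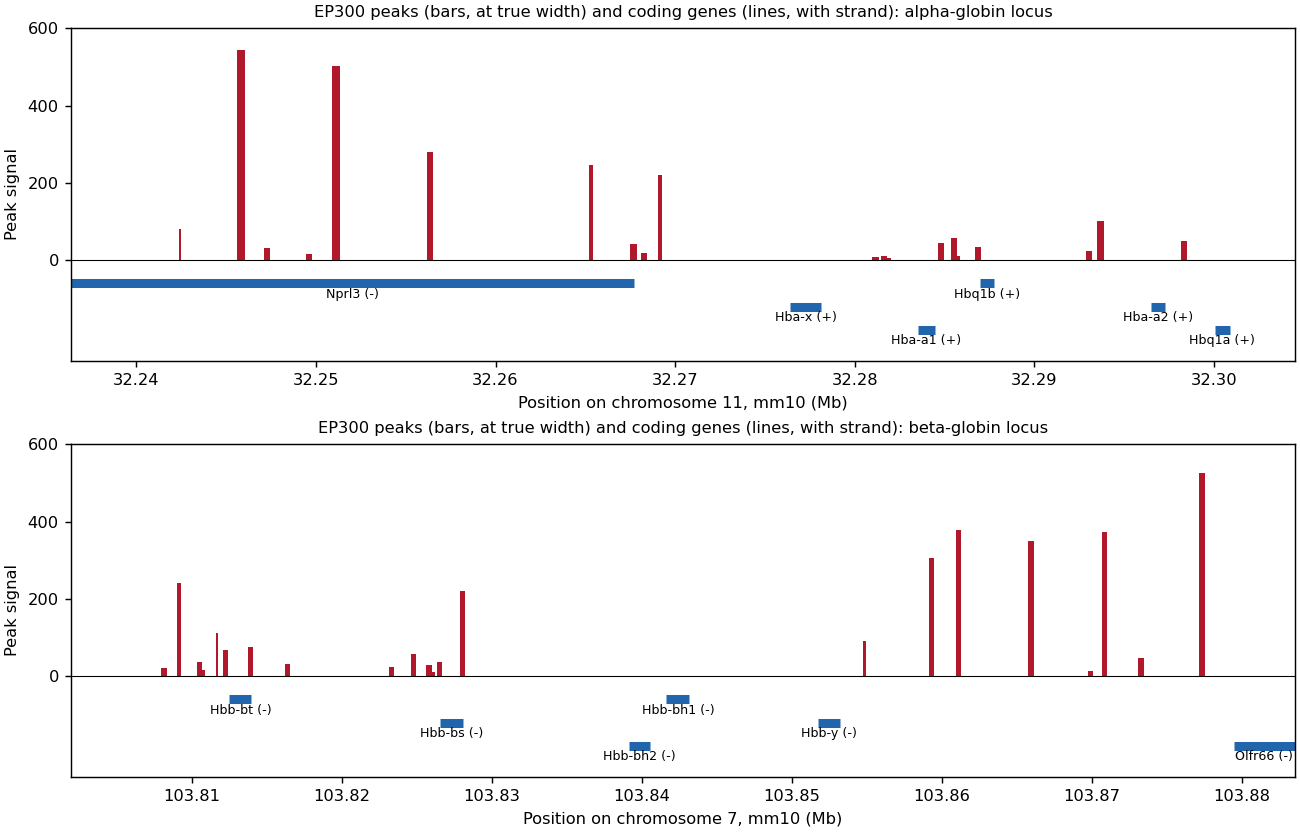
EP300 peaks of the optimal list at the alpha-globin locus (chromosome 11) and the beta-globin locus (chromosome 7), with position in Mb of mm10 on the x axis and peak signal on the y axis; each bar is a peak at its true width and each blue line a protein-coding gene with its strand. The highest bars, with signals of 544.1 and 525.5, stand in Nprl3 and upstream of Hbb-y, outside the globin genes.

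EP300 peaks lay at promoters more often than random positions, yet most were distal. Of the 17043 peaks, 4473 (26.2%, 95% interval 25.6 to 26.9) had a summit within 1 kb of a TSS, against 6.38% ± 0.179 of randomly placed summits (mean and SD of 1000 placements; two-sided permutation p = 0.002, the smallest that 1000 placements can give). Introns held 7534 peaks (44.2%, random placement 40.4%) and intergenic regions 4382 (25.7%, random placement 49.8%). A further 498 peaks lay in noncoding exons or untranslated regions and 156 in coding exons. Promoter peaks were weaker, with a median signal of 31.5 against 42.2 for the 12570 distal peaks. Most bases within 100 bp of the summit were repeat-masked in 4.14% of peaks, against 26.8% in 1 random placement, the one also used for introns and intergenic regions. The promoter share was 38.4% in the weakest decile of peaks, 29.3% in decile 9 and 16.5% in the strongest.

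Peaks also lay close to one another, as the runs at Zfpm1, Slc4a1 and the globin genes show. Another summit lay within the stitching distance of 63.8% of summits, against 16.4% ± 0.370 in 1000 random placements (one-sided permutation p = 0.001, the smallest possible). Random placements that kept each peak's distance to its TSS gave 39.5% ± 0.436.

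Almost every erythroid gene tested had an EP300 peak near it. Of 21728 protein-coding genes, 8385 (38.6%) had an optimal summit within 20 kb of a TSS. All 20 erythroid transcription factors had one (95% interval 83.9 to 100%; adjusted exact p = 3.7e-08), as did all 34 globin, membrane and receptor genes (89.8 to 100%; adjusted exact p = 1.8e-13) and 13 of 14 genes of heme synthesis and mitochondrial iron import (92.9%, 68.5 to 98.7; adjusted exact p = 1.6e-04). Tests on lists were two-sided Fisher's exact tests against the other protein-coding genes, adjusted by Benjamini-Hochberg over 21 lists, and each list call here was also made with every alternative peak list, window and background tried.

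Among the transcription factors, Gfi1b (signal 570.3, 12 peaks within 20 kb) and Zfpm1 (505.5, 21 peaks) were followed by Foxo3, which acts in the maturation of erythroblasts, with a peak of 467.9 in its intron, and by Lyl1, a basic helix-loop-helix factor, with a promoter peak of 375.8. The erythroid master regulators Gata1, Tal1 and Klf1 had strongest peaks of 217.2 on chromosome X from 7971372 to 7971615, 226.4 on chromosome 4 from 115056553 to 115056784 and 187.2 on chromosome 8 from 84901199 to 84901385. The Gata1 peak was intronic and the Tal1 and Klf1 peaks were at promoters.

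Among the membrane and globin genes, Gypc (509.5), the carbonic anhydrase gene Car2 (467.8, intergenic) and Xpo7 (432.5, intronic) had peaks among the 4 strongest. Slc4a1 had 23 peaks within 20 kb, the strongest 331.6 at its promoter on chromosome 11 from 102363646 to 102363950. Hba-a1 and Hbb-bs each had 14. In the heme pathway, the strongest peaks were at Cpox (459.3, promoter), the mitochondrial transporter gene Abcb10 (401.0), the ferrochelatase gene Fech (392.3, intron) and Alas2 (365.8, intron), the erythroid enzyme of the first step of heme synthesis. Slc25a37, named after its value was seen, was the member without a peak within 20 kb.

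Hepatocyte genes did not stand apart from other genes in how often they had a peak. A peak lay near 6 of 21 hepatocyte transcription factors (28.6%, interval 13.8 to 49.96; adjusted exact p = 0.445), 16 of 37 secreted protein genes (43.2%, 28.7 to 59.1; adjusted exact p = 0.678) and 12 of 33 metabolic enzyme and transporter genes (36.4%, 22.2 to 53.4; adjusted exact p = 0.903). The nuclear receptor gene Rxra (222.2, intron), the prothrombin gene F2 (118.8) and Fah, of tyrosine breakdown (319.2, intron), had the strongest peaks of the 3 lists. Of the hepatocyte products Alb, Afp and Apoa1, the first 2 had strongest peaks below the median signal, at 20.001, in a coding exon on chromosome 5 from 90463850 to 90464189, and at 22.7, 2203 bp from the TSS, and that of Apoa1 was near the median, at 41.7 in an intron of Sik3. Hnf4a had 1 peak, of 14.7, inside the gene and 5950 bp from its nearest TSS, and Cebpa had none within 20 kb and 1 within 50 kb.

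Taken as 2 sets, 67 of 68 erythroid and heme genes (98.5%, 92.1 to 99.7) and 34 of 91 hepatocyte genes (37.4%) had a peak within 20 kb, a difference of 61.2 percentage points (two-sided Fisher's exact p = 6.1e-18). For the secreted proteins the difference from other genes changed sign, never past the threshold, among alternatives: it was 4.66 points as tested, −11.5 points with peaks above the median signal and −4.63 points without replicate 1.

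Genes of growth and division also had peaks. All 24 cell cycle and DNA replication genes had a peak (86.2 to 100%; adjusted exact p = 1.2e-09), the strongest near Mcm2 (368.9), Mki67 (282.1), Mcm7 (276.6) and Aurka (260.8). The peak near Mcm7 lay in Taf6 and the peak near Aurka in an intron of Fam210b, so the 20 kb window does not say which gene a peak belongs to. With distal peaks alone, 15 of the 24 cell cycle genes had a peak, 35.8 points more than other genes in place of 61.5. Of 28 ribosomal protein genes, 24 had a peak (85.7%, 68.5 to 94.3; adjusted exact p = 2.0e-06), with the strongest near Rpl3 (341.7), Rps23 (276.5), Rps19 (167.4) and Rpl32 (142.9). With distal peaks alone, 13 of the 28 did (46.4% against 26.7% of other genes; adjusted exact p = 0.0694). Rpl30 had no peak within 50 kb.

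Of 17 coactivator genes, 14 had a peak (82.4%, 59.0 to 93.8; adjusted exact p = 0.0019), the strongest near Med1 (324.3), Med12 (241.3), Ncoa1 (189.0) and Kat2b (174.6). Ep300 itself had 2 peaks within 20 kb, the stronger (108.7) intergenic on chromosome 15 from 81577767 to 81577852 with a composite E-box and GATA site. Crebbp, the gene of its close relative, had 3, the strongest an intronic peak of 42.2.

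Among the other blood lineages, no list passed the threshold. A peak lay near 11 of 20 megakaryocyte and platelet genes (55.0%, 34.2 to 74.2, adjusted exact p = 0.245), led by F2rl2 (394.1, in an intron of Iqgap2). A peak lay near 12 of 22 stem and progenitor genes (54.5%, 34.7 to 73.1, adjusted exact p = 0.245), led by Lmo2 (328.0, promoter). Lmo2 and Tal1, each with a peak, are also on the erythroid transcription factor list. Both lists of this paragraph so far would have been called higher with each peak given to its nearest gene (adjusted exact p = 0.0197 and 0.0210). Megakaryocyte genes would also have been called with the 5 kb window and without replicate 2 (29.6 points, adjusted exact p = 0.0220), and progenitor genes with distal peaks alone. Counts were 4 of 24 for macrophage genes (16.7%; adjusted exact p = 0.0713), with the iron exporter gene Slc40a1 first (197.9, promoter), 5 of 21 for granulocyte and mast cell genes (23.8%; adjusted exact p = 0.245) and 6 of 22 for lymphoid genes (27.3%; adjusted exact p = 0.445). Macrophage genes were called lower in the top of the pooled list and with distal peaks alone (−23.0 and −22.6 points), and granulocyte genes were at −14.8 points as tested and at 7.15 without replicate 2. The strongest peaks near the last 2 lists lay in other genes, in Ccrl2 for Ltf (253.1) and at the promoter of Rps19 for Cd79a (167.4).

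Mesenchymal, neuronal and epidermal genes had peaks less often than other genes. Peaks lay near 2 of 21 stellate and mesenchymal genes (9.52%, 2.65 to 28.9, adjusted exact p = 0.0152). These were Reln (485.1, intergenic) and Tagln (56.2, in a coding exon of Sidt2), while Acta2 and Alcam had none within 50 kb. Neuronal genes, taken as genes outside the liver, had peaks in 3 of 26 cases (11.5%, 4.003 to 29.0, adjusted exact p = 0.0119). They lay in Gad2 (46.3), in Tubb3 (43.6) and, for Elavl3 (28.9), 19100 bp away at a promoter in Zfp653. None lay within 50 kb of Camk2a or Syn1. Epidermal genes had peaks in 2 of 20 cases (10%, 2.79 to 30.1, adjusted exact p = 0.0223). They lay in Tgm1 (39.6) and, for Dsc1 (16.4), in an intergenic region 16935 bp away. None lay within 50 kb of Casp14 or Col17a1. Each of these 3 calls was lost with peaks above the median signal, with nearest-gene assignment and with distal peaks alone. The stellate call was also lost in the conservative list and with the 5 kb window, the neuronal call with the 50 kb window, and the epidermal call with 1 gene per 100 kb, with logistic regression and without replicate 1 (−24.8 points, adjusted exact p = 0.0533).

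No other list stood apart: 13 of 24 endothelial genes had a peak (54.2%; adjusted exact p = 0.245), with Kdr, the VEGF receptor gene, first at 128.1; 3 of 15 cholangiocyte genes (20%; adjusted exact p = 0.245), led by Aqp1, a gene also on the erythroid list (354.1); 6 of 25 muscle genes (24.0%; adjusted exact p = 0.245), led by Ryr2 (353.9, intron); and 5 of 13 fetal growth genes (38.5%; adjusted exact p = 1), led by Hmga2 (100.6, intron). Myh6, a cardiac myosin gene, had none within 20 kb. Nearest-gene assignment put the fetal growth genes 38.2 points above the rest (adjusted exact p = 0.0155), and leaving out replicate 2 gave 5.68 points (adjusted exact p = 0.780).

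**Figure D3:**
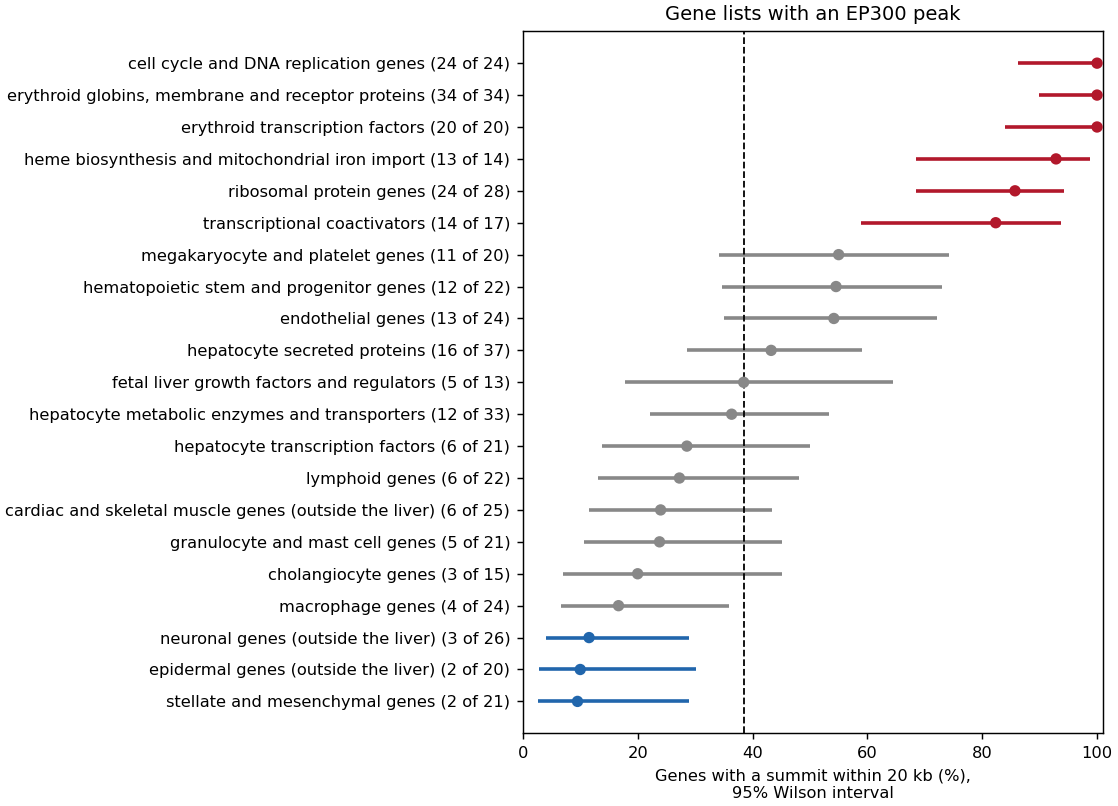
Share of the genes of each of 21 lists with an optimal EP300 summit within 20 kb of a TSS (x axis, percent; points with 95% Wilson intervals; red higher and blue lower than other genes at an adjusted p of 0.05, grey neither), with counts beside the names and the share of all 21728 genes, 38.6%, as a dashed line. The 3 erythroid and heme lists lie at 92.9% or above and the 3 hepatocyte lists between 28.6% and 43.2%.

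The strongest peaks near erythroid genes were also stronger than those near other genes. Each gene's strongest peak within 20 kb was ranked within the optimal list, and the median percentile was 93.8 for erythroid transcription factors (20 genes), 95.4 for globin, membrane and receptor genes (34 genes) and 96.2 for heme genes (13 genes), against 64.6 to 64.7 for other genes with a peak (two-sided permutation tests with 100000 draws, adjusted p = 2.1e-04, 1.6e-04 and 1.6e-04 over 16 lists). A strongest peak is expected to be higher where there are more peaks, and much of the difference went with peak number: against genes drawn with about as many peaks, an alternative added after seeing the data, the differences for the 3 lists fell from 29.1, 30.8 and 31.5 points to 8.80, 6.50 and 12.9 (adjusted permutation p = 0.0224, 0.00128 and 0.00715). Peaks near secreted protein genes of hepatocytes were weaker, with a median percentile of 22.4 against 64.9 (16 genes, adjusted permutation p = 5.6e-04), and 30.7 points lower against genes with about as many peaks (adjusted permutation p = 0.00715). That call was lost without replicate 1 (a difference of −29.4 points, adjusted permutation p = 0.147). The other 12 lists did not pass the threshold, among them hepatocyte transcription factors (25.2, adjusted permutation p = 0.0600, and 0.0158 against genes with about as many peaks), cell cycle genes (63.7, adjusted p = 0.906) and ribosomal protein genes (60.6, adjusted p = 0.830). Granulocyte and mast cell genes, 11.7 points higher as tested, turned lower when either library was left out, as given further below.

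GATA sites were the leading sequence feature of EP300 summits. WGATAR was found within 100 bp of the summit in 74.7% of the peaks and in the flanks, at 400 to 500 bp, in 29.5%. The longer AGATAAG was present in 24.7% against 2.49%, and the E-box and GATA composite in 21.7% against 1.14%. The composite was written as CTG and WGATAA 7 to 9 bases apart, after the site of the complex of TAL1 and GATA1. Some matches need not be that site. Each other spacing from 3 to 14 bases also had 350 to 514 peaks, against 794 to 1937 for spacings of 7 to 9. Of 24 motifs, 13 were more frequent at the centre and 2 less frequent (exact two-sided McNemar tests, Benjamini-Hochberg adjusted). For the 3 GATA forms p was below the smallest number the computation holds.

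Sites of several other blood factors were also more frequent at the centre. The CACCC box of KLF1 and its relatives was found in 14.6% of centres against 7.82% of flanks (adjusted exact p = 5.5e-90), the NFE2 site in 2.36% against 0.510% (adjusted exact p = 6.7e-50), the AP-1 site in 5.91% against 3.16%, RUNX in 4.31% against 2.20%, STAT in 2.80% against 1.77% and PU.1 in 1.53% against 1.19% (adjusted exact p = 0.0113). The AP-1 consensus is part of the NFE2 consensus, so every NFE2 match is also counted for AP-1. The PU.1 call was lost with peaks above the median signal and without replicate 1 (0.252 points, adjusted exact p = 0.0785). Sites of general promoter and structural factors followed: ETS 1.34% against 0.352%, the GC box of SP factors 2.30% against 1.26%, CTCF 0.698% against 0.147% and NRF1 0.745% against 0.329%. The GC box consensus holds a form of the CACCC consensus, so its matches are also counted there. Against shuffled sequence of the same dinucleotide content in place of the flanks, the excess was larger for CACCC (11.01 points in place of 6.78), the GC box (1.98 in place of 1.04), STAT (1.65 in place of 1.04), PU.1 (0.675 in place of 0.346) and NRF1 (0.657 in place of 0.417), and smaller for AP-1 (1.68 in place of 2.75).

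Sites of hepatocyte factors were not. HNF4A sites were found in 0.575% of centres and 0.487% of flanks (adjusted exact p = 0.370), CEBP in 1.55% and 1.28% (adjusted exact p = 0.0520), FOXA in 3.17% and 2.92% (adjusted exact p = 0.238), and HNF1 and ONECUT in 0.0704% and 0.106% of centres (adjusted exact p = 0.549 and 0.623). Against shuffled sequence, HNF4A and FOXA passed the threshold (0.194 and 1.06 points higher, adjusted exact p = 0.0159 and 2.6e-09), while CEBP changed sign (−0.176 points). GFI1B sites, of the repressor whose gene had the strongest peak, were found in 0.229% of centres and 0.334% of flanks (adjusted exact p = 0.116), and MEF2, REST and octamer sites did not pass the threshold either. NR5A (1.68% against 2.54%) and TEAD (5.64% against 6.23%, adjusted exact p = 0.0396) were less frequent at the centre; against shuffled sequence NR5A was 0.552 points more frequent, and the TEAD call was lost there, without replicate 1 (−0.405 points) and without replicate 2 (−0.499 points).

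**Figure D4:**
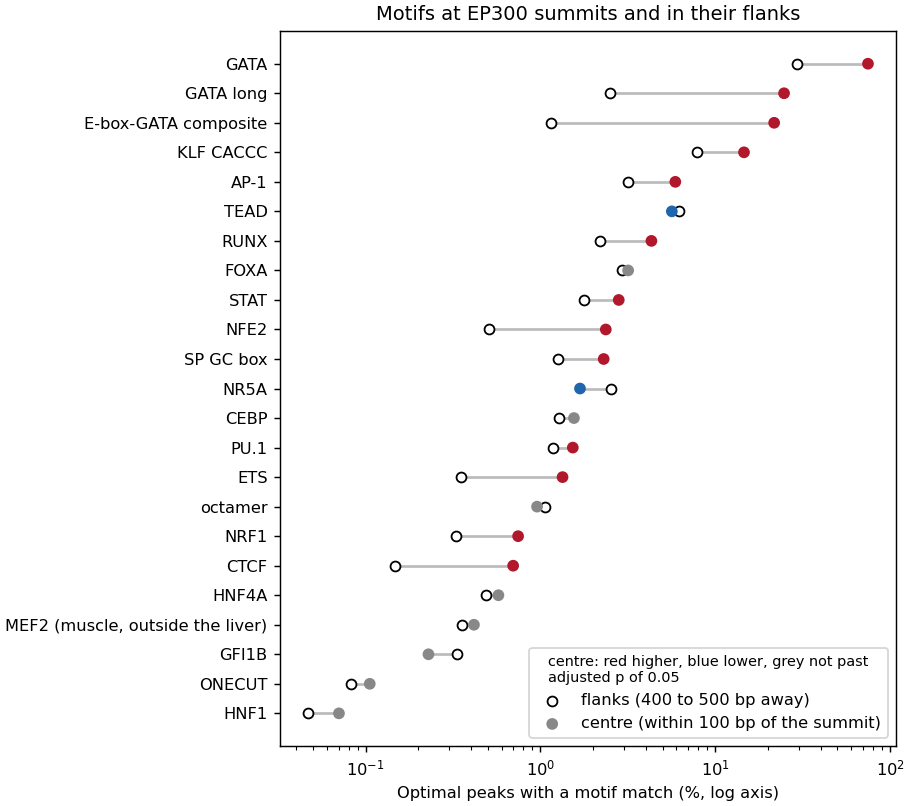
Share of the optimal peaks with a motif match (x axis, percent, log scale) within 100 bp of the summit (filled points; red higher and blue lower than the flanks at an adjusted p of 0.05, grey neither) and in flanks of the same total length at 400 to 500 bp (open points), for the 23 motifs with a match in both. GATA sites rise from 29.5% in flanks to 74.7% at the centre, and the composite site from 1.14% to 21.7%.

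GATA sites followed peak strength. The share of peaks with WGATAR was 94.7% in the strongest decile and 42.0% in the weakest, and the share with the composite site was 40.9% and 5.81%. A large step lay between decile 9, at 63.4% and 12.9%, and the weakest. The weakest decile holds the 616 peaks with a signal under 10, most of them within 500 bp of another optimal peak.

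**Figure D5:**
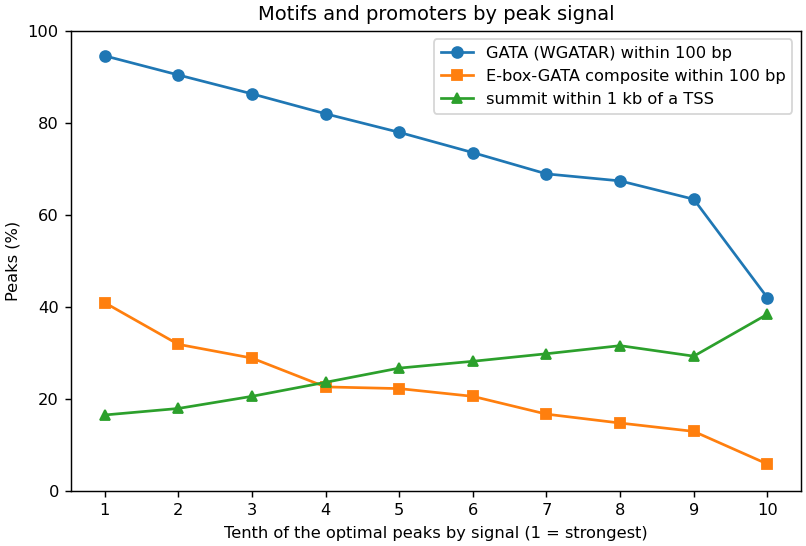
Share of peaks (y axis, percent) with a GATA site (circles) or an E-box and GATA composite (squares) within 100 bp of the summit, and with a summit within 1 kb of a TSS (triangles), in deciles of the optimal list by signal (x axis, 1 the strongest). From the strongest to the weakest decile, GATA sites go from 94.7% to 42.0% and promoter peaks from 16.5% to 38.4%, with 63.4% and 29.3% in decile 9.

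Promoter and distal peaks differed in their motifs. WGATAR was found in 42.1% of promoter peaks and 86.3% of distal peaks, and the composite site in 9.99% and 25.9%. ETS sites were found in 4.31% of promoter peaks and 0.278% of distal peaks, NRF1 sites in 2.59% and 0.0875%, GC boxes in 6.19% and 0.915% and CACCC boxes in 21.4% and 12.2%. In all, 12 of 24 motifs differed (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted). With each motif's excess over its own flanks, as a difference in log odds, 4 motifs differed: the 3 GATA forms were lower at promoters and ETS higher. CACCC and GC boxes then changed sign, at −0.254 and −0.125, both short of the threshold.

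Peaks near hepatocyte genes carried hepatocyte sites more often than peaks near erythroid genes. An HNF4A, CEBP, FOXA or HNF1 site was present in 11 of 53 peaks within 20 kb of hepatocyte genes (20.8%) and in 13 of 359 peaks within 20 kb of erythroid and heme genes (3.62%; two-sided Fisher's exact p = 4.0e-05). The difference of −17.1 points was −10.6 with the 50 kb window. A GATA site was present in 31 of the 53 (58.5%) and in 253 of the 359 (70.5%), a difference of 11.98 points that did not pass the threshold (Fisher's exact p = 0.0825). With each peak given to its nearest gene the GATA difference was 15.015 points and passed it (Fisher's exact p = 0.0261); it was 6.47 points without replicate 2, 0.380 with peaks above the median signal and 1.04 for AGATAAG.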

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

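The neighbour test of weak peaks below was chosen only after the result was seen.

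The unplaced contigs, which no comparison used, held 12 optimal peaks on 4 contigs, with signals from 10.8 to 44.0.

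The conservative list held 2352 peaks that were not in the optimal list, although the optimal list is the longer one. Their median signal was 16.9, 40.5% were at promoters and 50.6% had a GATA site, and 16.03% lay within 500 bp of an optimal peak.

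The optimal list held 616 peaks with a signal under 10, and 2251 of its peaks ranked beyond the first 17055 of the pooled list. Of the weak peaks, 83.6% (515) lay within 500 bp of another optimal peak, against 9.69% of the other 16427, so their IDR score may have come from a stronger neighbour; their median score was 795, against 630 for the weak peaks that stood alone and 1000 for other peaks. Summits of both libraries lay within 100 bp of 87.2% of other peaks, which were not split by neighbour. The shares were 6.80% for weak peaks beside another and 6.93% for those that stood alone. Among weak peaks, recurrence was thus about as low with a neighbour as without. The weak peaks beside another may also be separate sites. A GATA site lay within 50 bp of 19.3% of the 481 weak summits tested and of 12.47% of the positions mirrored across the stronger summit (difference 6.86 points, exact McNemar p = 0.0043). Nothing computed here excluded either explanation, and with 1 group no other biological explanation was tested. Without the peaks beside a stronger one, 59.1% of summits had another within the stitching distance, against 15.4% ± 0.389 at random.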

How the results depend on the processing

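The share of recurring top peaks, the promoter share, the clustering, the erythroid, heme, coactivator and cell cycle lists, the erythroid and hepatocyte contrast and the hepatocyte motif contrast kept their direction and their side of the threshold under all alternatives run. Of the alternative values of the main results, 286 did so, 16 lost the threshold, 8 gained it, 14 changed direction and 4 moved. Leaving out peaks beside a stronger one, an alternative chosen after seeing the data, changed no gene list call. For peak strength, draws matched for the number of peaks were also added after seeing the data. Where a value below changed, the cause was not tested. Read depth is unknown, and the lists of 13 to 37 genes leave wide intervals. No paired analysis was possible because there is only 1 group.

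Spearman's rho between the libraries was 0.916 with summits within 25 bp, 0.893 in the conservative list and 0.868 above the median signal. The gene lists moved as follows, as differences from other genes in percentage points. With peaks above the median signal, secreted proteins were at −11.5 and endothelial genes at −0.0415, both reversed, and the stellate (−15.5), neuronal (−17.4) and epidermal (−20.1) calls were lost. With the 5 kb window, secreted proteins reversed (−10.04), megakaryocyte genes were called (26.5) and the stellate call was lost (−18.8). With the 50 kb window, hepatocyte enzymes (6.93) and granulocyte genes (8.23) reversed and the neuronal call was lost (−15.2). With nearest-gene assignment, secreted proteins (−6.71) and fetal growth genes (38.2) reversed, megakaryocyte genes (29.0), progenitor genes (28.1) and the GATA contrast of erythroid and hepatocyte genes (15.015) passed, and the stellate (−21.5), neuronal (−15.7) and epidermal (−21.0) calls were lost. With distal peaks alone, enzymes (3.61) and fetal growth genes (4.07) reversed, progenitor (27.9) and macrophage genes (−22.6) passed, and the stellate (−17.2), neuronal (−19.0), epidermal (−16.7) and ribosomal (19.8) calls were lost. The stellate call was lost in the conservative list (−22.4), and macrophage genes passed in the pooled list (−23.0). With 1 gene per 100 kb and with logistic regression, fetal growth genes reversed (3.08 and 9.09) and the epidermal call was lost (−26.9 and −16.1). Leaving out each library in turn gave −4.63 to 5.48 for secreted proteins, −9.00 to 5.68 for fetal growth genes, −6.43 to 7.15 for granulocyte genes, 15.3 to 29.6 for megakaryocyte genes and −35.5 to −24.8 for epidermal genes.

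Against shuffled sequence, CEBP (−0.176), NR5A (0.552) and octamer sites (0.305) reversed, and with the narrow centre MEF2 did (−0.0176). HNF1 ran from −0.0235 to 0.0235 without either library. As a difference in log odds, 4 motifs separated promoter from distal peaks, and CACCC (−0.254), GC box (−0.125), PU.1 (0.111), STAT (−0.334), HNF4A (0.0353), ONECUT (−0.556), MEF2 (1.01) and octamer (0.336) reversed. With peaks above the median signal, STAT (−0.721), HNF4A (0.219), CEBP (0.130), HNF1 (0.0520), CTCF (0.0483), MEF2 (0.0706) and octamer (0.189) reversed between promoter and distal peaks, as did HNF4A (0.05003) and octamer (0.0651) in the conservative list. Of these reversals, that of NR5A was past the threshold on both sides, that of the octamer only against shuffled sequence, and those of CACCC and the GC box only as first tested; the others were short of it on both sides.

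Of peak strength, lymphoid (−14.6), endothelial (10.1) and muscle genes (6.55) reversed in the conservative list, endothelial (13) and cell cycle genes (1.40) in the pooled list, and lymphoid (−13.2), endothelial (4.08) and cell cycle genes (11.2) with the 50 kb window. With draws matched for the number of peaks, the fetal growth (5.63), coactivator (−0.261) and cell cycle lists (0.0880) reversed, all short of the threshold, hepatocyte transcription factors passed it (−42.0) and the erythroid and heme calls held at 6.50 to 12.9 points. Leaving out each library in turn gave −38.1 to −19.6 for granulocyte, −4.998 to 21.8 for lymphoid, 7.69 to 14.5 for endothelial, 3.39 to 6.67 for cell cycle, −5.08 to 9.23 for ribosomal and −29.2 to 8.92 for muscle genes; the granulocyte value of −38.1, without replicate 2, was past the threshold (adjusted permutation p = 0.0282).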

Other observations

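The gene families and the motif spacing described first, and the tests of gene number on the X chromosome and of the 50 kb window, were chosen only after results were seen.

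Histone genes carried EP300 peaks, and those at their promoters had GATA sites less often than other promoter peaks, a difference that was not tested. Of 67 genes named as histones, 59 (88.1%) had a summit within 20 kb, against 38.4% of other genes (two-sided Fisher's exact test, adjusted over 13 added lists, p = 2.2e-16). Neighbouring genes of a family can share a peak. Hist1h2af, Hist1h3g, Hist1h2bh and Hist1h3f had the same strongest signal, 204.4, as did Olfr66 and Olfr64, 525.5. The test takes genes as independent, so the p-values of the gene families below and above overstate the evidence. Taking 1 gene per 100 kb was tried for the 21 lists only. Of the 70 peaks within 1 kb of a histone gene TSS, 24.3% had a GATA site, against 42.3% of the other 4403 promoter peaks, and their median signal was 40.7 against 31.4. Genes of some other functions also had peaks. Of erythropoietin signalling and survival genes, 13 of 16 had one (adjusted exact p = 0.0013), the strongest near the survival gene Bcl2l1 (320.3). Of iron uptake and storage genes, 12 of 14 did (adjusted exact p = 5.9e-04), the strongest near the ferritin receptor gene Ncoa4 (330.4). Of autophagy and mitochondrial clearance genes, 14 of 16 did (adjusted exact p = 1.5e-04), the strongest near Becn1 (357.6). Bnip3l, a receptor for the removal of mitochondria, was lower, at 184.1. The first 2 of these lists share Epor, Stat5a and Stat5b, and Tfrc, with the erythroid lists called before, so they are not separate support for them. Glycolysis genes had peaks in 11 of 15 cases (adjusted exact p = 0.0088) and proteasome subunit genes in 24 of 40 (adjusted exact p = 0.0091). The share was low for olfactory receptors (37 of 1134, adjusted exact p = 1.7e-184), vomeronasal receptors (5 of 330, adjusted exact p = 1.1e-60), Hox genes (0 of 39, adjusted exact p = 2.1e-08), keratins (0 of 53, adjusted exact p = 3.4e-11), cytochrome P450 genes (11 of 100, adjusted exact p = 3.4e-09) and serpins (10 of 61, adjusted exact p = 4.8e-04), and 157 of 385 solute carrier genes had a peak (adjusted exact p = 0.370).

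The distance between the E-box and the GATA site was narrow. With 8 bases between CTG and WGATAA, 1937 peaks had a match within 100 bp of the summit, with 7 bases 1079 and with 9 bases 794, whereas each other spacing from 3 to 14 bases had 350 to 514. The composite motif fixed in advance covers these 3 spacings.

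Chromosome X held 322 optimal peaks, 1.97 per Mb (95% counting interval 1.76 to 2.20), against 4.801 to 11.6 per Mb on the autosomes, a ratio of 0.282 (0.253 to 0.315), although Gata1 and Alas2 lie there. Pooled peaks beyond the first 17055, nearer to background, gave a ratio of 0.417 (0.407 to 0.426), above that of the optimal list. Those of them up to rank 50000 gave 0.263 (0.242 to 0.285), which was not above it. The strongest decile of optimal peaks gave 0.113 (0.0653 to 0.194). Lower read coverage of X stays open, because the comparison turned on the rank cut and 0.417 is itself well below 1. Fewer genes on X were not enough to account for the difference: X had 0.340 peaks per protein-coding gene, with an upper bound of 0.379, and the lowest autosome 0.491. No biological explanation was tested, since the sexes were pooled and the design has 1 group.

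Hepatocyte genes did not have peaks more often than other genes, which may reflect binding below the threshold. Pooled peaks ranked from 17055 to 50000 lay within 20 kb of 62.6% of the 91 hepatocyte genes and 57.5% of other genes (two-sided Fisher's exact p = 0.340), and of 97.1% of the 68 erythroid genes, so whether hepatocyte genes gather such peaks cannot be told apart from the general rate with 91 genes. Of 151 such peaks near hepatocyte genes, 10.6% had an HNF4A, CEBP, FOXA or HNF1 site at the centre and 2.65% in the flanks (exact McNemar p = 0.0118). Near erythroid genes the shares were 5.31% and 3.18% (377 peaks, exact McNemar p = 0.215), and the difference between the groups of peaks was not tested. Binding below the threshold predicts an excess at the centre. Peaks of the optimal list were not removed from this set, however, and 2251 of them ranked beyond the first 17055 of the pooled list. The sites may therefore lie in peaks above the threshold, and the excess cannot decide the question. An optimal peak within 50 kb lay near 58.2% of hepatocyte genes and 53.7% of others (Fisher's exact p = 0.401), which leaves more distant peaks open as well. A lower share of hepatocytes than of erythroid cells in the pooled livers stays open, and was not tested.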
